A study of Caenorhabditis elegans with 2 samples.

How the data were processed

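Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole Caenorhabditis elegans whose own lin-29 gene had been given an EGFP tag by CRISPR, with an antibody against GFP, per the labels. The animals were L4 larvae collected at 49 hours and had been synchronised by starving newly hatched larvae. The series holds 1 group of 2 samples, which the labels number as biological replicates 1 and 2 and which have separate biosample entries. There is no second condition, and no control immunoprecipitation or input was analysed here.

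The deposited data were 8 peak lists in ce11 coordinates, per the labels: for each replicate a ranked list of candidate peaks and a thresholded list, and for the pooled replicates 2 ranked and 2 thresholded lists. The replicate lists were made from each replicate's own alignments and the series-wide lists from the alignments of both, per the file headers in the deposited manifests. The manifests name a further input of unstated role for all lists, and another for the thresholded lists. The aligner and the peak caller are not given in the sources used here. The lists were made with the irreproducible discovery rate (IDR), which ranks peaks by how well their order repeats between 2 inputs. The deposited score of each peak, made by the authors, runs up to 1000 and grows as the IDR falls. From the values, the lowest score kept in the thresholded lists, 830, stands for an IDR of 0.01. The deposited signal of each peak is the authors' peak caller's own value, whose scaling is not stated. Signal was therefore compared between groups of sites only within a list, and between the replicates only by rank. The series-wide ranked lists have a further 16 columns on the inputs compared, which were not used. The lists hold no read counts, so the sequencing depth of each replicate is unknown. All intervals cover counting error over sites only.

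One of the series-wide thresholded lists, termed here the pooled list, was the main set, and the other, which its name calls conservative, was an alternative. Each thresholded list was tied to the ranked list that contains all of its peaks. Peaks of a list that overlapped by 1 bp or more were merged into regions, called sites below, that keep the summit and signal of the strongest peak. Gene models came from the Ensembl release 115 annotation of WBcel235, the assembly that ce11 names, and sequence from the RefSeq genome of that assembly, whose chromosome names were matched to the lists. Coordinates are 1-based. Where the annotation gave a microRNA gene only a database code, the RefSeq symbol at the same coordinates was used.

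The tests, the gene lists and the rule for naming genes were fixed before the data were examined, as were most alternatives. Overlap between the replicates' own lists was tested with 100000 circular shifts of replicate 2's regions along each chromosome, one-sided. Agreement of signal was measured with Spearman's rho across sites and a permutation p from 100000 pairings. Sites are not independent replicates, so this p describes these lists only. The location of a summit was taken, in this order, as promoter (within 1000 bp upstream of a protein-coding gene's 5′ end), 5′ UTR, coding exon, 3′ UTR, intron or other intergenic sequence, and compared with 10000 circular shifts of all summits, two-sided. The share of sites on X and the share of autosomal sites in the middle 40% of each autosome were compared with 100000 draws of as many candidates from the ranked list, two-sided. A gene counted as having a site when a summit lay between 2000 bp upstream of its 5′ end and its 3′ end. The number of such genes in each of 20 lists was compared with 100000 draws of candidates, one-sided for an excess, with the p for a deficit kept beside it. Shares of summits within 500 bp of tRNA, rRNA, snRNA, snoRNA and miRNA genes were tested likewise. Each 6-mer, read on both strands, was compared by Fisher's exact test between the sequence within 50 bp of the summits and 2 windows of the same width centred 500 bp to either side. The leading 6-mer was chosen on chromosomes I, III and V and tested on II, IV and X. Differences in median signal were tested by permutation with 100000 resamples, two-sided, for lists with at least 5 summits. Benjamini-Hochberg adjustment was applied within each family, and adjusted p under 0.05 was the threshold. Intervals of shares are 95% Wilson intervals.

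The 20 lists held 1314 annotated genes: developmental timing (heterochronic) genes, collagens of the adult cuticle, all cuticle collagens, moulting and apical matrix genes, hedgehog-related genes, seam cell and hypodermal regulators, vulval and uterine genes, cell cycle, Wnt, TGF-beta, nuclear receptors, homeobox genes, lipid metabolism, markers of intestine, muscle, neurons and germline, male tail genes, and 2 lists of highly transcribed control genes, namely ribosomal protein and elongation factor genes and other housekeeping genes. Lists overlap, and 6 listed names (ram-4, ptc-2, cog-2, egl-29, opt-2 and lep-1) were not found in the annotation. Genes named in the text are 24 fixed genes of the timing pathway and the cuticle whether or not they had a site, the genes with the 5′ end nearest to the 20 strongest sites found in both replicates' lists, up to 5 members with the strongest sites of each list that passed, and the 10 genes with the most sites. Any other gene named was chosen after its values were seen.

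The alternatives were the conservative list, the stronger part of the sites by signal, each replicate's own list in place of the pooled one, unmerged peaks, other overlap rules, promoter widths of 500 and 2000 bp, a gene window from 1000 bp upstream to 500 bp downstream of the 5′ end, the nearest 5′ end only, distances of 200 and 1000 bp, k of 5 and 7, windows of 25 and 100 bp, and other backgrounds. Alternatives chosen after the data were seen were draws from the 5000 candidates with the highest score, candidates matched on GC content in 10 groups, sites away from highly transcribed control genes, and sites and candidates in single-copy sequence. Single-copy sequence meant that at least 90% of the 31-base words within 50 bp of the summit occur at a single place on the 6 chromosomes. In the tests of explanations a ratio of 1.5 or less, or an adjusted p of 0.05 or more, was written beforehand as what a technical cause would give. The first code asked for both together, which left GC content at timing genes undecided, and it was changed to the written rule after that result was known. Changes of direction between tests that both failed to pass were at first counted as unchanged, and the count was corrected after the results were known. Which individual genes and lists counted as main results in these comparisons was also set after the data were seen.

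The tests were tested on simulated data drawn from the real candidates and genome. Over 40 sets of 856 random candidates, 0.263% of the lists were called with nothing planted, and 15 planted sites in the muscle list were found in 85% of sets. Random genome positions gave 0 enriched or depleted 6-mers and 0 of 20 pairs with an overlap p under 0.05. Random candidates gave 47 of 2080 6-mers with nothing planted, so candidates as such differ from their flanks. The held-out Fisher's exact test of the leading 6-mer then gave p = 0.645, and p = 1.4e-10 with a 6-mer planted in 10% of the windows. Pairs of random draws from 1 candidate list passed the overlap test in 7 of 20 cases while sharing at most 6 regions, so the shifts are a weak background for lists that draw on common candidates. The null sets of random genome positions were added after the first simulation, made with candidates alone, had called 6-mers and overlaps with nothing planted. Null sets of signal gave p under 0.05 in 7 of 100 median tests. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and matplotlib 3.10.9 for the plots.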

Results

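Binding of LIN-29, a zinc finger transcription factor that ends the developmental timing (heterochronic) pathway and drives the larval-to-adult switch of the epidermis, was profiled in L4 larvae by ChIP-seq of an EGFP-tagged protein. Both samples are biological replicates of the same whole-animal material, so the comparisons are between the replicates and between sites and their genomic background. The pooled list held 906 peaks, which merged into 856 sites with a median signal of 79.9. Replicate 1's own list held 528 sites and replicate 2's 381, out of 41736 and 43151 candidate regions. The depth of the libraries is unknown, because the lists carry no read counts.

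Most of replicate 2's sites were also found in replicate 1. The 2 lists shared 272 sites, which are 51.5% of replicate 1's (95% Wilson interval 47.3 to 55.8%) and 71.4% of replicate 2's (66.7 to 75.7%). Circular shifts gave a mean of 1.06 shared sites and at most 49 (permutation p = 1e-05, the smallest the 100000 shifts can give). Of the 256 sites found in replicate 1 alone, 201 (78.5%) had a candidate peak of replicate 2 within 100 bp, and of the 109 found in replicate 2 alone, 84 (77.1%) had a candidate of replicate 1. Signal at the 272 shared sites was correlated across sites (Spearman rho = 0.781, permutation p = 1e-05, the smallest possible), and rho was 0.574 over the 803 pooled sites with a candidate in both replicates. Among the 856 pooled sites, 267 lay in both replicates' lists, with a median signal of 146. Another 293 lay in neither list, with a median signal of 64.04. The conservative list had 802 sites, of which 693 overlapped the pooled list.

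**Figure D1:**
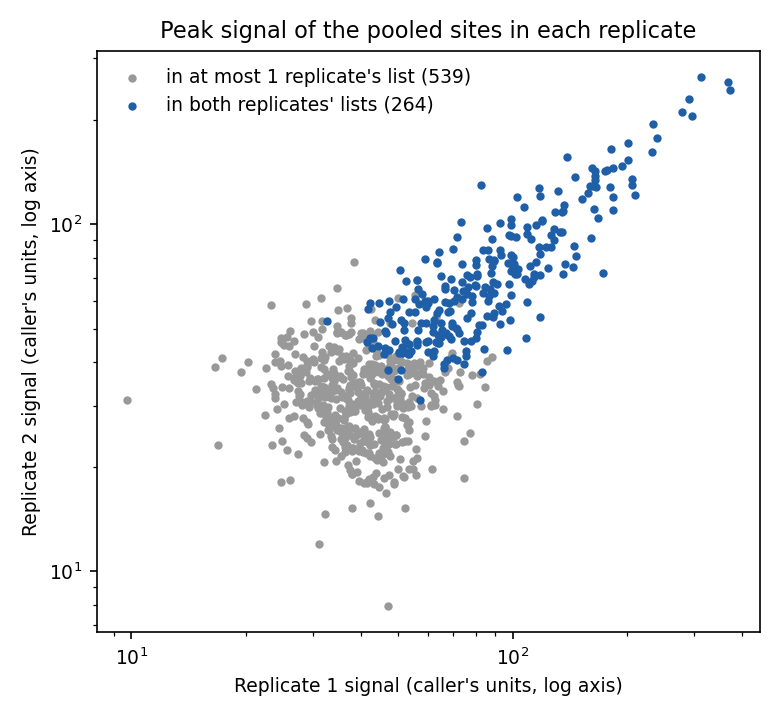
Peak signal of 803 pooled sites with a candidate within 100 bp in both replicates, replicate 1 on the horizontal and replicate 2 on the vertical log axis, in the peak caller's units. The 264 blue points are sites in both replicates' own lists and the 539 grey points are the other sites, and the 20 strongest pooled sites are all blue.

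The highest signal, 625, was on chromosome IV at 4727926 to 4728164 (ce11), in intergenic sequence 3175 bp downstream of the 5′ end of K08F11.1, and the next highest, 608, was at 4725483 to 4725721 near the same gene. The third lay 290 bp upstream of rpl-3, a large-subunit ribosomal protein gene (chromosome III, 3867448 to 3867697, signal 575 pooled, 313 in replicate 1 and 265 in replicate 2). The site 148 bp upstream of F44E5.4, an Hsp70 family gene on chromosome II, had a signal of 521, and the site 62 bp upstream of tasp-1, a threonine aspartase gene on III, had 415. Further sites among the 20 strongest lay in the promoters of rpl-35 (375), mog-4 (341), cdc-48.1 (332), Y22D7AL.10 (330), drr-2 (326), rpa-2 (324) and nspc-17 (309), and between Y17G9B.5 and rpl-20 (425). Other sites of this group had K07D4.2 (497), C34C12.1 (487), W02H3.3 (409), F20B6.9 (367), Y116A8A.150 (349) and K08D10.11 (314) as the nearest 5′ ends. The C34C12.1 site lay 2074 bp downstream of that 5′ end, past the gene's 3′ end and in a 5′ UTR of another gene. Sequence at the 3 K08F11.1 sites and at the Y116A8A.150, mog-4, rpa-2 and K08D10.11 sites is repeated in the genome, with a single-copy share between 0 and 40.8%, whereas it is 100% at rpl-3, F44E5.4 and tasp-1.

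A site lay in the window of 920 of 19973 protein-coding genes, and 154 sites lay in no such window. The gene with the most sites was tos-1 on chromosome V, with 5, the strongest 81 bp upstream (signal 194), followed by pqn-41 on III with 4. There were 3 sites each at Y111B2A.12, pro-1, daf-16 (the FOXO transcription factor of insulin signalling), Y43F8B.2, lin-42, mnk-1, F26F12.3 and ccch-1. In all 11 genes had 3 or more sites, and ties for the 10 named were broken by the strongest signal. The daf-16 site with the highest signal, 135, was intronic, 19474 bp from the 5′ end.

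Developmental timing genes carried more sites than candidate draws gave: 10 of 29 had a site, against 4.02 expected (2.49 times, 95% range of draws 1 to 8, permutation test, adjusted p = 0.0192 over 20 lists). The strongest were nhl-2, which codes for a TRIM-NHL cofactor of microRNAs (signal 233 pooled, 134 and 94.5 in replicates 1 and 2, 828 bp upstream on III), and puf-9, a Pumilio family gene (194 pooled, 102 and 91.7, 287 bp upstream on X). They were followed by ain-1, a GW182 family gene (118.99), lin-42, the Period homologue (110), and kin-20, a casein kinase gene (101). The remaining members with a site were lin-46 (97.3), the microRNA gene lin-4 (72.9), the Argonaute gene alg-1 (67.3), lin-29 itself (65.7) and sea-2 (65.4). The strongest sites at kin-20, lin-4, alg-1, lin-29 and sea-2 were in neither replicate's own list, and that at ain-1 only in replicate 1's. All of them were in the conservative list. The call was lost with candidates matched on GC content (1.77 times, permutation test, adjusted p = 0.211), with draws from the 5000 highest-score candidates (1.11 times, adjusted p = 1), with the nearest 5′ end only (2.17 times, adjusted p = 0.186) and among the 428 strongest sites (2.82 times, adjusted p = 0.102). Each replicate's own list lost it too, with 5 members in each (1.76 times, permutation test, adjusted p = 0.955 in replicate 1, and 2.54 times, adjusted p = 0.263 in replicate 2), while the other alternatives kept it with adjusted p from 4.09e-06 to 0.0403. Among those, the ratio was larger with the narrow window around the 5′ end (10.5 times), by Fisher's exact test over coding genes (8.50 times) and against circular shifts (4.31 times). The narrow window held 6 members with a site against 0.571 expected, so that ratio rests on a very small expected number. This window also raised the ratio of ribosomal (12.6 times), housekeeping (9.61 times) and cell cycle genes (6.90 times, with 0.435 expected). It did not raise that of all lists, with neurons at 0.913. Fisher's exact test takes no account of candidates in the window, with a median of 8 for timing genes and 2 for all protein-coding genes.

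**Figure D2:**
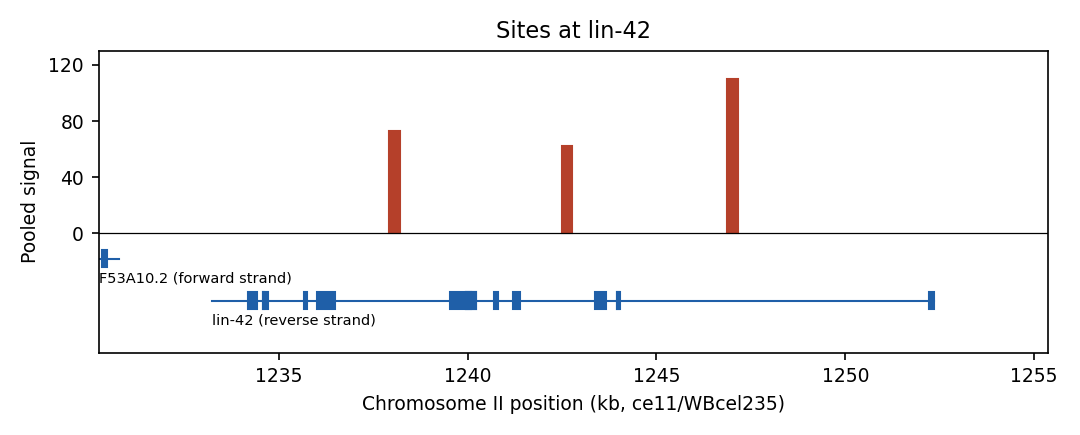
Sites at lin-42 on chromosome II (horizontal axis, position in kb, ce11/WBcel235), drawn as bars whose width is the site and whose height is the pooled peak signal in the caller's units. Blue boxes are coding exons of the annotated genes, and the 3 sites, with signals of 73.2, 61.95 and 110, lie in lin-42 introns.

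Of the 24 genes of the timing pathway and the cuticle fixed in advance, 4 had a site. The 3 lin-42 sites were at 1237926 to 1238215, 1242488 to 1242777 and 1246871 to 1247160 on chromosome II. The lin-46 site (V, 12967872 to 12968161) lay 838 bp upstream of that gene, which acts downstream of lin-28, with signals of 51.1 and 52.8 in replicates 1 and 2. The lin-29 site (II, 11917687 to 11917976) was in the 3′ UTR of the gene that carries the tag, with signals of 28.8 and 40.2, below the threshold in each replicate's own list. The site in an intron of nhr-23, a nuclear receptor gene needed for moulting (I, 7217249 to 7217538, signal 65.6), was in neither replicate's list and not in the conservative list. No site was found for mab-10, lin-41, let-7, lin-28, lin-14, hbl-1, daf-12, blmp-1, nhr-25, mlt-10, col-17, col-19, bli-1, rol-6, cki-1, aff-1, eff-1, egl-18, lin-3 or dpy-7. The strongest candidate in the window of mab-10, whose product is a cofactor of LIN-29, had an IDR of 0.0230, that of lin-14 0.0159 and that of lin-41 0.0789. The candidate at col-19, an adult-specific collagen gene, had an IDR of 0.423.

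Ribosomal protein and elongation factor genes had the largest excess of the 20 lists in the main test, with 27 of 87 genes against 3.76 expected (7.18 times, range of draws 1 to 8, permutation test, adjusted p = 2e-04, from the smallest p the draws can give). By Fisher's exact test their ratio, 6.74 times, was below that of the timing genes, 8.50 times. The strongest members of the ribosomal list were rpl-3, rpl-20, rpl-35, rpl-15 (signal 299) and rps-1 (247), each within 421 bp upstream of the 5′ end. Other highly transcribed control genes followed with 10 of 33 against 2.28 expected (4.39 times, permutation test, adjusted p = 8e-04), led by the chaperone genes hsp-90 (179) and hsp-1 (164), the ATP synthase gene atp-1 (177), the tubulin gene tba-1 (147) and hsp-3 (132). Draws from the 5000 highest-score candidates lowered the first excess to 2.48 times and ended the call of the second (1.44 times, permutation test, adjusted p = 1). Over all alternatives the ratio ran from 2.48 to 12.6 times for ribosomal and elongation factor genes and from 1.44 to 9.61 times for the other control genes. Both lists were fixed in advance as places where any tagged protein can give signal, and no control immunoprecipitation was analysed here.

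None of the other 17 lists passed, for an excess or a deficit. Where few genes were expected, a deficit could not have passed. With 0 genes the unadjusted permutation p for a deficit was 0.526 for adult cuticle collagens, 0.277 for intestine and 0.201 for male tail genes. Cuticle collagens had 8 of 177 genes with a site against 7.98 expected, led by col-94 (signal 159), and collagens of the adult cuticle had 0 of 11 against 0.616. The ratio for all cuticle collagens, 1.00 in the main test, depended on the background: it was 0.458 with GC matching and 0.452 against the 5000 highest-score candidates, where 8 genes lie below the range of draws (10 to 26) but the deficit did not pass (permutation test, adjusted p = 0.170 and 0.118). It was 1.66 against circular shifts and 1.80 with the narrow window, where no excess passed. Moulting and apical matrix genes had 5 of 35 against 3.65, hedgehog-related genes 4 of 85 against 5.17, and seam cell and hypodermal regulators 2 of 24 (nhr-23 and ajm-1) against 2.05. Vulval and uterine genes had 3 of 33 against 3.12 (egl-17, him-4 and lin-35), Wnt genes 3 of 28 against 2.29 (lit-1, mig-5 and pry-1) and TGF-beta genes 2 of 22 against 2.03 (daf-5 and sma-9). Cell cycle genes had 3 of 25 against 1.52 (cye-1, efl-1 and lin-35), and passed only with the narrow window around the 5′ end (6.90 times, 0.435 expected, permutation test, adjusted p = 0.0436). Nuclear receptors had 9 of 274 against 12.9, lipid genes 2 of 77 against 5.03, and homeobox genes 1 of 93 (ceh-38) against 4.66, the only deficit with an unadjusted p under 0.05 (permutation p = 0.0482, adjusted p = 0.742). Among markers of other tissues, neurons had 6 of 170 against 5.75, muscle 1 of 30 against 3.51 (unc-60), germline 1 of 77 against 2.62 and intestine 0 of 27 against 1.24, and male tail genes had 0 of 21 against 1.48. Members named here for lists that did not pass, other than nhr-23, were chosen after their values were seen.

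**Figure D3:**
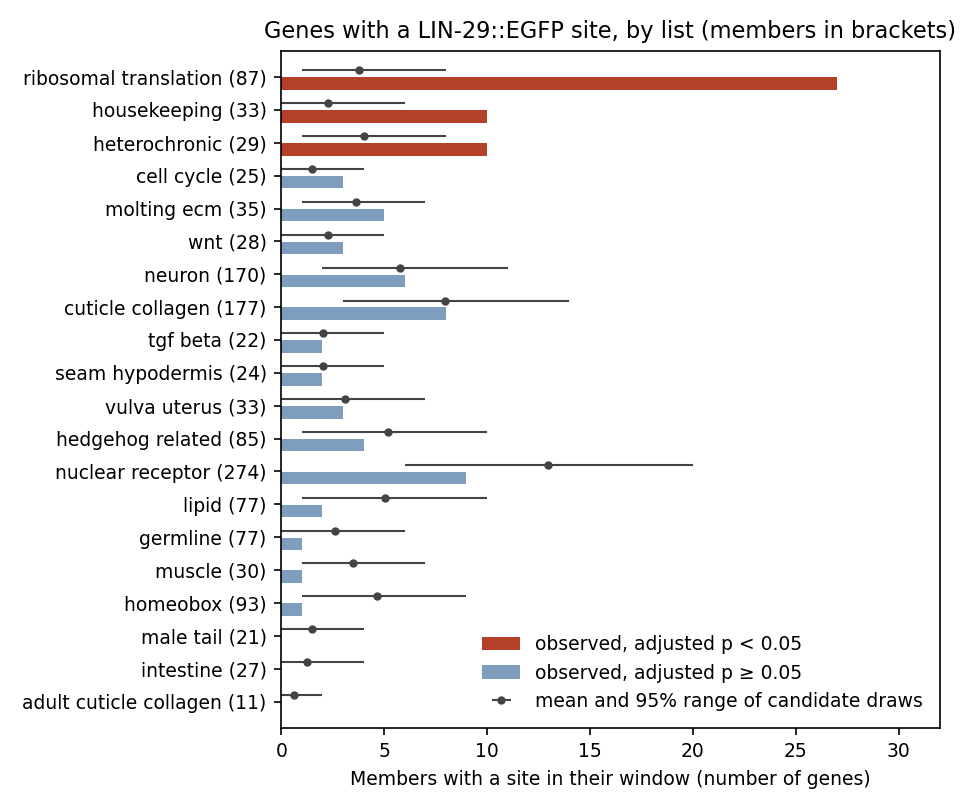
Number of genes with a site in each of the 20 gene lists (bars, list sizes in brackets), beside the mean (points) and 95% range (lines) of 100000 draws of candidate peaks. Red bars mark the 3 lists with adjusted p under 0.05: ribosomal and translation genes at 27, housekeeping genes at 10 and heterochronic genes at 10.

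Sites were more frequent near tRNA, snoRNA and snRNA genes than candidates were. There were 128 sites (14.95%) within 500 bp of a tRNA gene, against 0.975% of candidates (15.3 times), and 150 of the 612 annotated tRNA genes had a site this near. For snoRNA genes 53 sites (6.19%) compared with 0.631% (9.81 times), and for snRNA genes 14 sites (1.64%) with 0.181% (9.03 times). Each of these had permutation p = 1e-05, the smallest the draws can give, and adjusted p = 1.67e-05. Draws from the 5000 highest-score candidates lowered the ratios to 2.87 times for tRNA, 2.89 times for snoRNA and 2.82 times for snRNA genes. GC matching left 8.28 times for tRNA genes, and the median single-copy share at tRNA sites was 57.0%, against 100% at the other sites. Few of the strongest sites lay near a tRNA gene: 4 of the top 100 by signal, against 61 of the next 328 and 63 of the weaker 428. MicroRNA genes had 9 sites (1.05%) against 0.370% (2.84 times, permutation test, adjusted p = 0.006), but the excess was not seen among the 428 strongest sites (0.234%) or in replicate 2's own list (0.262%), and was not called with a distance of 200 bp, in replicate 1's list, or against the highest-score candidates. No site lay near an rRNA gene. A candidate 23 bp from the rRNA gene rrn-4.2 (V, 17122916 to 17123205, signal 78.4) was left out of the pooled list. Its score reached the lowest score kept.

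Sites concentrated in promoters. Of the 856 summits, 372 (43.5%, 95% Wilson interval 40.2 to 46.8%) lay within 1000 bp upstream of a protein-coding gene, against 17.9% in shifts (2.43 times, permutation p = 2e-04, the smallest two-sided value the shifts can give, adjusted p = 4e-04). Coding exons held 5.02% of summits against 21.5%, 3′ UTRs 0.935% against 2.44% (permutation test, adjusted p = 0.0018) and introns 23.8% against 31.8%, all below the shifts. The deficit in introns was not called against the 5000 highest-score candidates (permutation test, adjusted p = 0.106). 5′ UTRs, with 2.22% against 1.52%, did not pass (permutation test, adjusted p = 0.168), but did so in replicate 2's own list (3.41%) and without sites near highly transcribed control genes (3.03%). Other intergenic sequence held 24.5% against 24.9% in shifts (permutation test, adjusted p = 0.859), but lay above the 21.1% of candidate draws (permutation test, adjusted p = 0.0170). The median distance from a summit to the nearest 5′ end was 902 bp, and 337 summits lay within 500 bp of it. The promoter excess was 3.70 times with a promoter width of 500 bp, 1.63 times with 2000 bp and 1.75 times against the 5000 highest-score candidates.

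**Figure D4:**
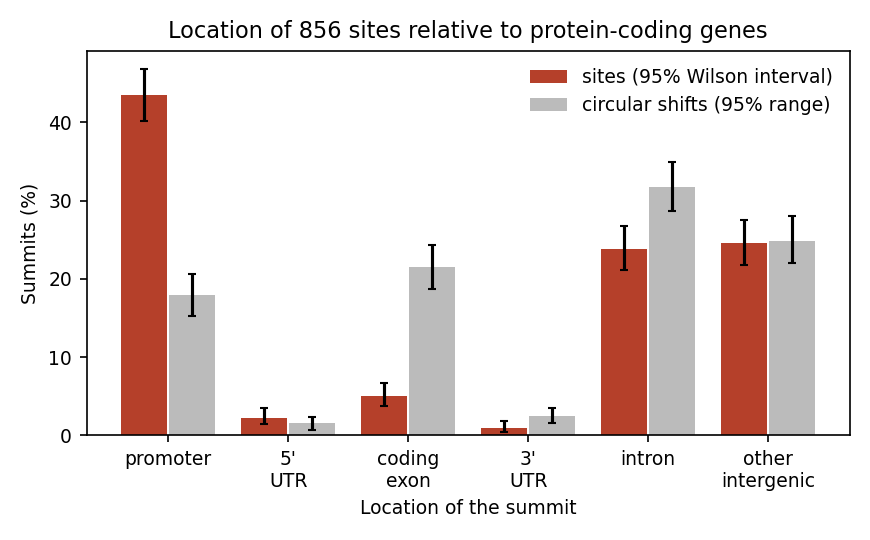
Share of the 856 summits in each class of sequence around protein-coding genes (red bars, with 95% Wilson intervals) beside the mean of 10000 circular shifts (grey bars, with their 95% range), in percent. Promoters hold 43.5% of summits against 17.9% in shifts, and coding exons 5.02% against 21.5%.

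Chromosome X held 186 sites (21.7%), against 17.999% in candidate draws (permutation test, adjusted p = 0.00538), and the middle 40% of the autosomes held 298 of 670 autosomal sites (44.5%) against 38.4% (adjusted p = 0.00188). Relative to length, sites were most frequent on I (1.24 times) and X (1.23 times) and least on V (0.750 times) and IV (0.757 times). Neither excess passed among the 428 strongest sites, where X held 21.5% and the middle of the autosomes 42.3%. Nor did either pass in the replicates' own lists, where X held 21.3 to 21.4% and the middle 41.2 to 41.7%.

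Sequence at the summits was rich in G and C, with a median GC content of 49.5% within 50 bp of the summit, 35.6% in the flanks 500 bp away and 40.6% at candidates. The leading 6-mer was ACGCAG, present at 147 sites (17.2%) and in 2.28% of flanks (odds ratio 8.81, Fisher's exact test, adjusted p = 5.14e-37). On the held-out chromosomes II, IV and X it was present at 17.5% of sites and in 3.15% of flanks (odds ratio 6.44, Fisher's exact test, p = 5.12e-18). This test takes sites and flanks as independent. Of the 856 sites, 124 had a single-copy share below 50%, so held-out sites may repeat sequence of the other chromosomes. GAGAGA was present at 21.96% of sites against 5.78%, ACGCGC at 12.5% against 1.34% and GCGCGC at 9.23% against 0.818%. Runs rich in A were rarer at the summits: AAAAAT was present at 23.5% of sites against 47.8%, and AAAAAA at 24.3% against 38.6%. Of 2080 6-mers, 569 were enriched and 419 depleted. Against candidates matched on GC content 495 passed in all, and ACGCAG kept an odds ratio of 4.19. The leading 6-mer chosen on I, III and V then became GAGAGA, with an odds ratio of 2.91 on the held-out chromosomes.

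**Figure D5:**
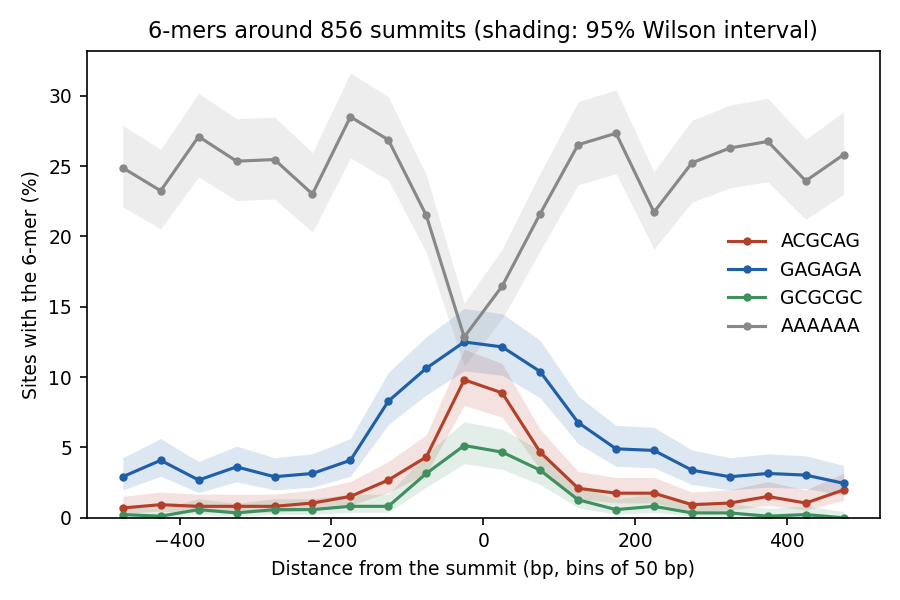
Share of the 856 sites with each of 4 6-mers (vertical axis, percent) in bins of 50 bp by distance from the summit (horizontal axis, bp), with 95% Wilson intervals as shading. ACGCAG, GAGAGA and GCGCGC peak in the bins beside the summit, where AAAAAA is lowest.

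Sites at ribosomal protein and elongation factor genes were stronger than the rest, with a median signal of 128 at 26 sites against 79.4 at the other 830 (difference 48.6, permutation test, adjusted p = 9.1e-04 over 7 lists). The difference did not pass among the 428 strongest sites (22.2). In replicate 1's own list (18.9) it had a permutation adjusted p of 0.0593 over the lists tested there and 0.0279 over the 4 comparisons by location, and in replicate 2's list (23.4) it passed in both. The 13 sites at developmental timing genes had a median of 73.2 against 79.9 (permutation test, adjusted p = 0.664), and no other list passed. Promoter sites had a median of 83.8 against 76.4 elsewhere (difference 7.33, permutation test, adjusted p = 0.00186), a difference that did not pass among the 428 strongest sites (11.96). Sites on X, with a median of 79.7 against 79.9 on autosomes, did not differ by the permutation test (adjusted p = 0.904). Sites at housekeeping genes, with a median of 107 against 79.8, did not pass by permutation over the lists tested (adjusted p = 0.147, and 0.125 with unmerged peaks) or over the 4 comparisons by location (0.0555), where only unmerged peaks gave a pass (0.0401).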

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

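The test of sequence copies in this part was chosen after these regions had been seen and before its own result was known. The ranked list behind the pooled list holds 22 candidate peaks whose score reaches the lowest score kept but which the thresholded list leaves out. They are counted unmerged and called left-out regions here, and those on I at 10947413 to 10947702 and 10947700 to 10947989 overlap. They drew attention because they enter the comparisons only as part of the candidate background, never as sites. The strongest is on chromosome X at 15810981 to 15811161 (ce11), in intergenic sequence 861 bp from an annotated pseudogene. Its signal of 1602.6 is above the 625 of the strongest site kept, and replicates 1 and 2 give it 876 and 848 in their own candidate lists. Another left-out region of this kind, with a signal of 141, lies on X at 15808048 to 15808337, and 12 of the 22 lie within 10000 bp of another.

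Repeated sequence is a candidate explanation for why these regions were left out. The median share of 31-base words within 50 bp of their summits that occur at a single place in the genome was 0%, with 21 of 22 regions below 50%, and the median at the sites kept was 100%. However, 124 of the 856 sites kept (14.5%) were also below 50%, among them the strongest sites, near K08F11.1. A low single-copy share alone therefore did not lead to a region being left out. The words at the strongest left-out region occur at a median of 30 places, and those at the strongest site kept at a median of 5. Over the left-out regions this median ran from 1 to 41. Whether the number of copies separates left-out regions from sites kept was not tested. The explanation met the bound set for it in a test that could have come out otherwise, but whether the authors removed the regions for this reason is not stated in the sources used here. The thresholded lists have a further input of unstated role, which could have served to exclude regions, and this was not tested. The region on II at 2570724 to 2571013, within usp-39, is the exception, with a single-copy share of 100%. No biological explanation was tested, since the series has 1 group.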

How the results depend on the processing

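Draws from highest-score candidates, GC matching, the removal of sites near control genes, single-copy sequence and the pooled set size without each replicate were chosen after the data were seen. Over 517 alternative values for 54 results, 418 kept their direction and side of the threshold (or, for counts, stayed within 1.5 times), 21 were weaker, 4 stronger, 11 moved and 63 changed direction, 3 of these with a value past the threshold in either test. Promoter, tRNA and ribosomal gene excesses and the overlap of the replicates passed under every alternative run for them. With draws from the 5000 highest-score candidates the number of lists called fell from 3 to 1, timing genes to 1.11 times and housekeeping genes to 1.44 times. Without sites near control genes 1 of the 18 lists left was called, the timing genes. All 10 timing genes with a site kept it. The candidates drawn from were not filtered, and fewer were drawn, so the expected number fell from 4.02 to 3.03. That call therefore does not separate the timing excess from signal at control genes. Timing genes were not called with GC matching (1.77), the nearest 5′ end only (2.17), the 428 strongest sites (2.82) or without replicate 1 or replicate 2 (1.76 to 2.54). For X and the middle of the autosomes the shares were 21.5% and 42.3% among the strongest sites, and 21.3 to 21.4% and 41.2 to 41.7% without each replicate. The count of k-mers moved from 988 to 495 with GC matching, to 356 and 1530 with k of 5 and 7, where another number of k-mers is tested, and to 615 without replicate 1 (727 without replicate 2). The number of lists with stronger sites, adjusted over lists, fell from 1 to 0 among the strongest sites and without replicate 2 (1 without replicate 1), where ribosomal genes differed by 22.2 and 18.9 (23.4 without replicate 1). Among the strongest sites the promoter difference was 11.96. The pooled set had 428 sites in its stronger part, 381 without replicate 1 and 528 without replicate 2, by construction. The 3 changes of direction with a passing value were microRNA genes at 0.234% of the strongest sites and 0.262% without replicate 1 (0.758% without replicate 2), and other intergenic sequence, 24.5%, against candidate draws. The other 60 passed in neither test. Ratios of gene lists that crossed 1 were, for cuticle collagens, 0.981 by Fisher's exact test, 0.458 with GC matching, 0.452 with highest-score candidates, 0.964 unmerged, 0.852 in single-copy sequence, 0.992 among the strongest sites, 0.851 without control sites and 0.717 to 1.37 without each replicate. For neurons they were 0.913 with the narrow window, 0.766 by Fisher's exact test, 0.728 in the conservative list, 0.996 unmerged, 0.870 single-copy, 0.683 strongest, 0.938 without control sites and 0.569 to 1.103 without each replicate. For vulval genes they were 3.93 narrow, 1.97 Fisher, 1.13 shifts, 1.39 conservative, 1.12 highest-score, 1.87 strongest and 1.54 to 2.29 without each replicate. For TGF-beta genes they were 1.97 Fisher, 1.39 shifts, 1.05 conservative, 1.05 nearest 5′ end, 1.18 single-copy, 1.32 without control sites and 0.723 to 1.07 without each replicate. For seam genes they were 1.81 Fisher, 1.24 shifts, 1.36 nearest 5′ end, 1.23 single-copy and 0.843 to 1.23 without each replicate. For Wnt genes they were 0.947 conservative, 0.895 nearest 5′ end, 0.836 strongest and 0.794 to 1.87 without each replicate. For moulting genes they were 0.852 conservative, 0.527 strongest and 0.583 to 0.843 without each replicate. Hedgehog-related genes had 1.02 Fisher, 1.08 shifts and 1.22 highest-score, male tail genes 1.22 with the nearest 5′ end, and muscle and nuclear receptors 3.08 and 1.24 with the narrow window. Timing gene signal differed by 28.3 with the narrow window, 0.786 among the strongest sites and 2.88 to 20.9 without each replicate, and signal on X by 0.799 in the conservative list and -2.06 to 3.13 without each replicate. Against highest-score candidates 5′ UTRs (2.22%) lay below and other intergenic sequence (24.5%) above, and the latter held 32.1% with a 500 bp promoter and 24.4 to 26.9% without each replicate. Elsewhere the cause was not tested. Replicate lists hold fewer sites, which limits those tests, and depth is unknown. No paired analysis was possible because the series has 1 group.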

Other observations

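The test of candidates just below the threshold was chosen after its result was seen, and the other tests in this part after the excess they examine and before their own result, except that the median single-copy share of tRNA sites was known when the ratio in single-copy sequence was predicted.

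Candidates that missed the threshold lay in the windows of timing genes, housekeeping genes and collagens more often than draws gave. Of 692 candidate regions with an IDR above 0.01 and up to 0.05 outside the sites, some lay in the windows of 12 of 29 timing genes, against 3.32 expected (3.62 times, permutation test, adjusted p = 8e-04), and 2.91 times with GC matching (adjusted p = 0.004). The 9 of these genes without a site were daf-12, hbl-1, lep-2, lin-14, lin-28, mab-10, blmp-1, din-1 and lep-5, so that 19 of 29 timing genes had a site or such a candidate. Housekeeping control genes had the larger ratio, with 9 of 33 (4.86 times, permutation test, adjusted p = 9e-04, and 3.68 times with GC matching, adjusted p = 0.0057), so this excess is not particular to timing genes. The bound for timing genes was written after the value was seen, so the value describes these data and lends the idea no weight. Cuticle collagens, which had no excess of sites, had 18 of 177 genes with such a candidate (2.78 times, permutation test, adjusted p = 0.00147), among them bli-2 and sqt-3, but 1.69 times with GC matching (adjusted p = 0.167). Near tRNA genes lay 49 of the 692 candidates (7.08% against 0.975%, 7.26 times, permutation test, adjusted p = 5e-05). Near rRNA genes, which had no site, lay 2 (0.289% against 0.0163%, 17.7 times, permutation test, adjusted p = 0.0064), so that ratio rests on very few candidates. The permutation test also passed for snRNA (4.82 times, adjusted p = 0.00255), snoRNA (3.20 times, adjusted p = 0.00045) and miRNA genes (2.74 times, adjusted p = 0.0148).

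The excess of sites near tRNA and ribosomal protein genes shrank with stricter backgrounds but stayed. Draws from the 5000 highest-score candidates left 2.87 times for tRNA genes and 2.48 times for ribosomal genes. GC matching left 8.28 and 4.38 times, and every one of these ratios had an adjusted p under 0.05. GC content alone therefore does not account for these excesses. The 5000 candidates contain the sites themselves and are not matched to them on score. Those draws therefore cannot decide whether a property of strong candidates accounts for the excesses. Reads shared between tRNA gene copies cannot be told apart as a cause for most tRNA sites, because their median single-copy share of 57.0% (bootstrap 95% interval 47.9 to 68.3%) lies between the bounds set, but among 28 tRNA sites in single-copy sequence the ratio was 8.80 times, which argues against it there. Signal that any tagged protein gives at highly transcribed genes stays open, since no control immunoprecipitation was analysed here. No biological explanation was tested, because the series has 1 group.

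For the timing genes, random lists matched on the number of candidates per window held fewer genes with a site. Of 23 protein-coding members 9 had a site, above the upper end, 7, of the 95% range of 10000 random lists matched on that number (mean 3.21, one-sided permutation p = 0.002). Draws from candidates already take that number into account, so the matched lists largely repeat the main test and are not separate support. The match was not on window width, so wide windows as such stay undecided. The nearest 5′ end only, which uses no window, ended the call (2.17 times), while the narrow window around the 5′ end kept it (10.5 times, with 0.571 genes expected). So small an expected number makes that ratio uncertain, and it decides nothing on window width. A property of all strong candidates stays open, since draws from the 5000 highest-score candidates expected 9.01 genes (95% range 5 to 13) where 4.02 (1 to 8) were expected before, and left 1.11 times. Those candidates come from the same immunoprecipitation and contain the sites. The ratio therefore cannot tell such a property from weaker LIN-29 binding at the same genes. GC content also stays open, since matching raised the expected number to 5.64 (2 to 10) and left 1.77 times, with the call ended because 10 genes are no longer outside the draws after adjustment. Both met the bounds set for them, GC content by its adjusted p alone, so the excess at timing genes could come from either, and LIN-29 binding to its own pathway remains an untested hypothesis. No biological explanation was tested, because the series has 1 group.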
